A study of Mus musculus with 12 samples.

How the data were processed

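Total RNA from whole mouse lung was hybridised as biotin-labelled cRNA to an Affymetrix 3-prime expression array, 1 sample per array. The 12 arrays fall into 4 groups of 3: wild-type mice and mice labelled PPTA knockout, each sampled 8 h after surgery. The surgery was either cecal ligation and puncture (CLP), a model of abdominal sepsis, or a sham operation. PPTA is an older name of Tac1, the gene for preprotachykinin A, from which substance P is made. Groups were taken from the labels. The labels name triplicates but do not say whether these came from separate animals, so p-values measure the spread between these samples, which may in part be technical. A strain (Balb/c) is given for the wild type and not for the knockout, so strain and genotype cannot be separated.

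The deposited values are linear signal intensities per probe set. The labels name GCOS, MAS5 and the Affymetrix Expression Console as the software of the authors, without versions, roles or order. The mean signal between the 2% lowest and the 2% highest values was 150.001 on every array, so the deposited signal had been scaled to a common target, and no sign of further normalisation between arrays was seen. The array medians ran from 31.1 to 38.4. The table holds signals for 45101 probe sets, with no missing values and no detection calls. For arrays, their number limits the precision.

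After the 64 control probe sets were left out, 45037 remained. Values were used as log2 of the signal plus 3.47, which is 10% of the median of the array medians (34.7). This pseudocount pulls folds of weakly expressed genes towards 0. A probe set was tested if its signal was above the array median on at least 3 of the 12 arrays, which left 24574. The platform table pairs 34945 probe sets with 1 symbol, 932 with several and 9160 with none. Of those with 1 symbol, 34741 were matched to a RefSeq gene table of assembly GRCm38.p6, used for names, chromosomes and neighbouring genes only. Only probe sets with 1 symbol are named. A gene was represented by its probe set with the highest mean log2 signal, which gave 11862 genes.

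Differences between groups were tested with limma 3.58.1 in R 4.3.3: 1 linear model with 4 group means, contrasts, and moderated statistics with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe set was called at an adjusted p under 0.05. Contrasts were CLP against sham in each genotype, the difference of these responses (the interaction), knockout against wild type after each surgery, and the averages over genotype and over surgery. Adjusted p-values in the text come from limma unless another test is named. The size of the response in both genotypes was compared over the probe sets called for CLP on average, as the ratio of mean log2 changes, each signed by the direction of the average change. Its two-sided exact permutation test exchanged genotype labels within each surgery (400 assignments). It is exact only if genotype makes no difference after either surgery, so its p does not test equal responses alone. Single measures per array were compared by exact permutation tests, which cannot go below p = 0.1 with 3 arrays against 3.

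Gene lists for 21 processes and 23 cell types were fixed before the data were examined, as were the comparisons, their tests, the alternatives and the rule for naming genes. Of these 44 lists, 43 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01 between genes and, as an alternative, with a correlation estimated per list. Adjustment was over the lists of a contrast. Members called are counted over all probe sets tested and also adjusted over the list alone. A list of hepatocyte markers was written after the counts of calls had been seen and before its test. Camera compares a list with all other genes. Markers describe transcripts in whole tissue, not cell numbers.

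The rule for naming genes takes, per contrast, the 10 largest called rises and the 10 largest called falls whose arrays do not overlap between the groups compared (no overlap is not asked of the interaction). It also takes, for each called list or list with at least 3 called members, the 4 members with the smallest p and any that move against the list, every measured member of the tachykinin system, and up to 2 members of lists not called, with values only. In the interaction it also allows members of lists described for CLP, with both responses.

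The alternatives were quantile normalisation, centring of each array on its median, a pseudocount of 50% of the median, a floor in place of the pseudocount, no filter, a filter of 9 arrays, moderation without trend or with robust estimation, array weights, the replicate number as a block, probe sets with a cross-hybridisation suffix left out, only the 2 groups compared, at least a 2-fold change, the mean of a gene's probe sets, and each array left out in turn. The tests were also run on simulated data of the same size, with 100 changed probe sets per fold size among 24574. Of 2-fold changes, 72% were recovered for CLP in the wild type, 63% for CLP in the knockout, 33% for the interaction, and 68% for each comparison of genotypes. Of 4-fold changes, 98%, 96%, 78%, 96% (after sham) and 94% (after CLP) were recovered in the same order. Simulated groups shared the same spread per probe set, so these rates leave out unequal spread between the real groups. The rates for CLP in the wild type and in the knockout differ only by the draw. A simulated response ratio of 1.5 was estimated at 1.48 with a permutation p of 0.085 in a single draw. The simulated sham groups did not differ by genotype, so this draw does not show which ratios would pass. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, from tables read with pandas 2.3.3. No array was left out of the comparisons. Raw scans were not used here.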

Results

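Transcripts were measured in 12 whole-lung samples, 3 in each of 4 groups: wild type after sham surgery, wild type 8 h after CLP, and the same surgeries in mice labelled PPTA knockout. CLP opens the cecum so that gut bacteria spill into the abdomen, and the lung is injured from a distance. Substance P is a neuropeptide of sensory nerves that widens vessels and draws leukocytes. By the labels, the comparisons ask how the lung responds to sepsis with and without its precursor gene. The Tac1 signal went against those labels, as given below. The first principal component of the 24574 probe sets tested held 46.0% of the variance and the second 21.9%. Correlations between arrays of a group were 0.983 to 0.985 in wild-type sham, 0.937 to 0.981 in knockout-labelled sham and 0.952 to 0.973 in knockout-labelled CLP, and 0.985 for each pair in wild-type CLP. Array 3 of knockout-labelled sham stood apart from its group. On it 646 probe sets were at least 2-fold higher and 758 at least 2-fold lower than on both other arrays, against at most 33 and 78 on any wild-type array. In knockout-labelled CLP the numbers were 202 and 471 on array 3 and 92 and 329 on array 1, and on array 1 of knockout-labelled sham 83 and 105. The ratio of 3-prime to 5-prime beta-actin signal, a measure of RNA quality, was 1.38 ± 0.0903 (SD) in knockout-labelled CLP, 1.51 ± 0.0655 in knockout-labelled sham and 1.53 ± 0.0895 in wild-type CLP. The two-sided exact permutation p was 0.1 for both comparisons with knockout-labelled CLP, the smallest possible. The Gapdh ratio was 0.756 ± 0.0826 in knockout-labelled CLP and 0.764 ± 0.0351 in knockout-labelled sham (permutation p = 0.9). It was higher in wild-type CLP (0.878 ± 0.0304) and wild-type sham (0.821 ± 0.0178), with a permutation p of 0.1 for genotype after either surgery and for CLP in the wild type. Array medians were 32.1 ± 1.08 in knockout-labelled CLP and 38.1 ± 0.390 in knockout-labelled sham, against 33.3 ± 0.837 and 36.1 ± 0.768 in the wild type.

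**Figure D1:**
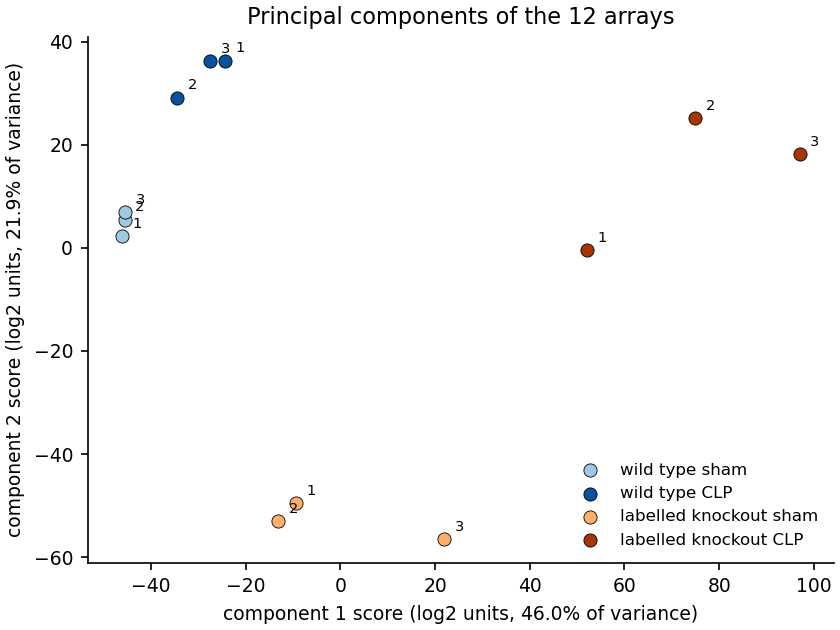
Scores of the 12 arrays on the first and second principal components of log2 signal, with the share of variance on each axis; colours mark the 4 groups. The wild-type arrays lie close together by surgery, and array 3 of knockout-labelled sham lies away from the other arrays of its group.

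Tac1 was the check of the genotype label, and it went against it. The Tac1 probe set that passed the filter gave 5.46 ± 2.78 (SD) in wild-type sham and 10.8 ± 6.21 in wild-type CLP. It gave 450.4 ± 75.8 in knockout-labelled sham and 413 ± 67.1 in knockout-labelled CLP. The log2 difference of knockout-labelled from wild-type arrays was 5.70 ± 0.33 (SE) after sham (adjusted p = 4.3e-07) and 4.97 ± 0.33 after CLP (adjusted p = 1.1e-06), with no overlap between arrays. With a pseudocount of 50% of the median the differences were 4.35 and 3.95, since the wild-type signal is near the floor. A second Tac1 probe set, below the filter, read 1.26 to 16.0 on all 12 arrays. The position of either probe set relative to the disrupted part of the gene is not given in the sources used here, so neither reading shows whether the peptide precursor could be made. H2-Ea encodes a class II histocompatibility chain that some mouse strains do not express. Its more strongly expressed probe set read 2342 to 2919 on the wild-type arrays and 57.0 to 83.0 on the knockout-labelled arrays. The direction of every genotype difference given here is that of the labels.

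**Figure D2:**
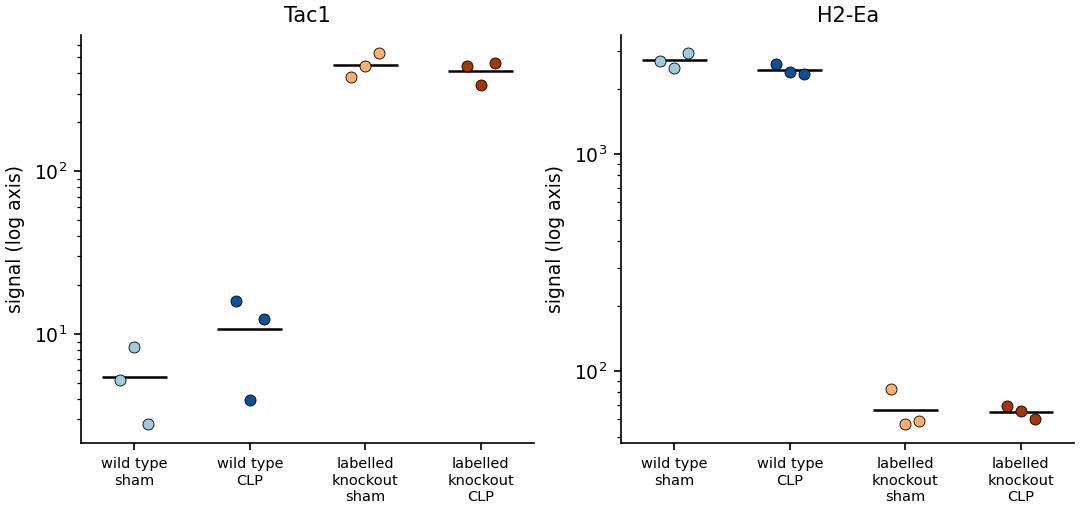
Signal (log axis) of Tac1 and of H2-Ea on each of the 12 arrays, by group; points are arrays and lines are group means. Tac1 is high on the 6 knockout-labelled arrays and low on the 6 wild-type arrays, and H2-Ea is the reverse.

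In wild-type mice the question was what the lung does within 8 h of abdominal sepsis. Transcripts of chemokines that draw neutrophils, of neutrophils and of feedback genes that restrain these signals rose, in lists called with the preset and with an estimated correlation. Transcripts of receptors that sense microbes were called as a list with the preset only. In all, 200 probe sets rose and 33 fell of 24574 tested, 158 and 22 of them at least 2-fold. With each gene counted by its representative probe set alone, 131 genes rose and 7 fell. For every gene named below as a largest rise or fall between groups, the arrays of the groups compared did not overlap. Among the largest rises was Acod1 (1427381_at), the enzyme with which activated macrophages make itaconate, from a signal of 4.08 ± 3.002 to 1016 ± 312 (log2 change 7.10 ± 0.48 SE, adjusted p = 2.4e-05). Its sham signal is near the pseudocount, so the size of the change depends on it: 5.55 with a pseudocount of 50% of the median and 7.77 with a floor. Cxcl2 (1449984_at), a neutrophil-attracting chemokine, went from 73.7 ± 34.2 to 7440.0 ± 245 (6.70 ± 0.46, adjusted p = 2.4e-05). Its relative Cxcl3 (1438148_at) rose by 6.28 ± 0.35 (adjusted p = 5.5e-06), or by 5.01 with that larger pseudocount. Il1b (1449399_a_at), the cytokine interleukin-1 beta, went from 451 ± 211 to 3431 ± 296 (3.05 ± 0.35, adjusted p = 0.0014). Il1r2, the decoy receptor that binds it, rose by 3.04 ± 0.31 (adjusted p = 4.9e-04). Rises of 4.31 and 2.96 were seen in Clec4e and Clec4d, C-type lectins that recognise microbial glycolipids. Rises were 3.55 in the neutrophil cysteine protease inhibitor Stfa3 and 3.44 in the monocyte chemokine Ccl3. The falls were smaller: Hey1 (-1.42) and Sox7 (-1.12), transcription factors of endothelium, and Id3 (-0.77), an inhibitor of differentiation factors, were among the 7 genes. These falls and some of the rises rest on few arrays. With 1 array left out, Hey1 and Id3 were called in 3 of 12 runs, Sox7 and Ccl3 in 4, Clec4d in 7 and Stfa3 in 10. The highest adjusted p was 0.25 for Hey1, 0.25 for Id3, 0.23 for Sox7 and 0.094 for Clec4d without array 1 of wild-type CLP, and 0.21 for Ccl3 and 0.059 for Stfa3 without array 3 of that group.

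Of 43 gene lists, 18 lay higher than other genes after CLP in the wild type and none lower. Another split of the same arrays called 19 lists, so this count alone does not set CLP apart from sham. Mature neutrophil markers had 10 of 13 measured members called up (12 adjusted over the list alone) with a median of 1.65 (adjusted p = 1.9e-30 with the preset and 0.015 with an estimated correlation). Their called members with the smallest p were Mmp9, a gelatinase of neutrophil granules (1.65 ± 0.13), Il1r2, Trem1, a receptor that amplifies myeloid activation (2.31 ± 0.26), and Stfa3. Markers of granulocyte precursors had 2 of 5 up (4 adjusted over the list alone), Ngp (2.07 ± 0.19) and the antimicrobial peptide gene Camp (2.14 ± 0.37), with a median of 1.28 (adjusted p = 8.5e-08 with the preset and 0.015 with an estimated correlation). Neutrophil-attracting chemokines had 3 of 6 up, both overall and adjusted over the list alone, with a median of 1.73 (adjusted p = 4.7e-11 with the preset and 0.0044 with an estimated correlation). Anti-inflammatory and feedback regulators had 8 of 19 up (14 adjusted over the list alone), among them Nfkbiz, an inducible regulator of NF-kappaB (2.58), Socs3, which damps cytokine receptors (2.22), and Zfp36, which destabilises cytokine mRNA (1.59; adjusted p = 6.4e-26 with the preset and 0.043 with an estimated correlation). Those 4 lists kept their call with an estimated correlation. Among their members Camp was called in 8 of 12 runs with 1 array left out (adjusted p up to 0.099) and Socs3 in 10 (up to 0.054), both highest without array 3 of wild-type CLP, and Zfp36 in 7 (up to 0.093 without array 1 of wild-type sham). Pattern recognition lost it (adjusted p = 1.2e-19 with the preset and 0.10 with an estimated correlation), with 10 of 24 up (13 adjusted over the list alone), led by Cd14, the co-receptor for endotoxin (2.88 ± 0.22). The other 13 lists called with the preset had medians from 0.06 to 0.64 and estimated-correlation adjusted p from 0.1 to 0.55. Among these, CC chemokines had 3 of 16 up, proinflammatory cytokines 1 of 13 (4 adjusted over the list alone) and acute phase proteins 2 of 16 (4 adjusted over the list alone), the metallothioneins Mt1 and Mt2. Platelet markers were called in 7 of 12 runs with 1 array left out (adjusted p up to 0.13). NK cell markers were called in 10 of 12 (up to 0.26) and in 7 of 11 other alternatives (up to 0.16). Coagulation genes were not called with quantile normalisation (adjusted p = 0.068). Lists of alveolar, airway, endothelial, fibroblast and muscle markers had no member called.

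The number of probe sets called in the wild type depends on single arrays and on the shared estimate of spread. Without array 1, 2 or 3 of wild-type sham it was 68, 119 or 90, and without array 1, 2 or 3 of wild-type CLP 52, 99 or 51. It was 432 without array 3 of knockout-labelled sham, 357 without array 1 of knockout-labelled CLP, 1308 with array weights and 1281 with only the 2 groups in the model.

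In knockout-labelled mice the same question was asked of the response to CLP. With the preset correlation, lists of neutrophil genes, cytokines, acute phase proteins and matrix regulators lay higher and lists of ciliated cell and muscle markers lower, but no list kept its call with an estimated correlation. Here 2553 probe sets rose and 4619 fell, 891 and 1268 at least 2-fold. By their representative probe sets, 1356 genes rose and 2359 fell. The median log2 change of all tested was -0.12, and it moved to 0.01 with arrays centred on their medians. That centring turned the balance of calls from 35.6% up to 56.6% up, so the excess of falls is relative to the deposited scaling. Acod1 rose by 7.67 ± 0.48 (SE, adjusted p = 4.6e-06), or by 5.72 with a pseudocount of 50% of the median. Il6 (1450297_at), a cytokine that drives the acute phase, went from 14.98 ± 15.5 (SD) to 2279 ± 1601 (6.82 ± 0.66, adjusted p = 6.0e-05). Camp (1419691_at) went from 98.4 ± 52.01 to 4213 ± 650.4 (5.54 ± 0.37, adjusted p = 5.5e-06). Saa3 (1450826_a_at), a serum amyloid made in inflamed tissue, went from 182 ± 129 to 6786 ± 2761 (5.35 ± 0.43, adjusted p = 2.7e-05). Other large rises were in the chemokines Cxcl3 (6.76), Cxcl2 (6.51), Ccl3 (6.001) and Ccl2 (4.93), in Csf3, which drives neutrophil production (5.53), and in the interleukin-1 receptor antagonist Il1rn (5.52). With the larger pseudocount the rises were 5.82 for Il6, 5.55 for Cxcl3, 5.397 for Ccl3, 4.17 for Csf3 and 4.41 for Ccl2. The largest fall was in Hspa1b (1452318_a_at), an inducible heat shock protein of the Hsp70 family, from 1498 ± 1244 to 109 ± 46.9 (-3.50 ± 0.49, adjusted p = 5.1e-04), with its close relative Hspa1a at -2.46. Its sham level was uneven, with 619, 2921 and 954 on the 3 arrays. Gli2 (-2.94 ± 0.29) and Gas1 (-2.36) of hedgehog signalling, the Wnt ligand gene Wnt3a (-2.38) and the retinoid-storing enzyme gene Lrat (-2.54) fell too (Gli2 at -1.60 with the larger pseudocount), and Lrat was called in 9 of 12 runs with 1 array left out (adjusted p = 0.079 without array 2 of knockout-labelled sham).

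With the preset correlation 21 lists lay higher and 3 lower in knockout-labelled CLP. Acute phase proteins had 13 of 16 up with a median of 2.37 (13 adjusted over the list alone; adjusted p = 5.7e-12 with the preset and 0.074 with an estimated correlation), including Saa3, Mt1 (2.46), the iron-siderophore binder Lcn2 (2.87) and orosomucoid, Orm1 (4.80). Granulocyte precursor markers had 4 of 5 up with a median of 2.95 (adjusted p = 7.5e-07 with the preset and 0.055 with an estimated correlation). Mature neutrophil markers had 11 of 13 with 1.84 (13 adjusted over the list alone; adjusted p = 4.5e-10 with the preset and 0.077 with an estimated correlation). CC chemokines had 10 of 16 up with a median of 1.65 (11 adjusted over the list alone; adjusted p = 2.6e-07 with the preset and 0.11 with an estimated correlation), against which the fractalkine receptor Cx3cr1 fell (-1.45, not called without array 3 of knockout-labelled CLP, adjusted p = 0.053). Proinflammatory cytokines had 8 of 13 up (adjusted p = 2.9e-06 with the preset and 0.17 with an estimated correlation). Feedback regulators had 18 of 19 up (adjusted p = 4.0e-15 with the preset and 0.074 with an estimated correlation). Matrix proteases and inhibitors had 10 of 16 up, led by Timp1, an inhibitor of matrix proteases (2.92 ± 0.19; adjusted p = 7.5e-07 with the preset and 0.074 with an estimated correlation). Alveolar macrophage markers had 6 of 13 up with a median of 0.65 (adjusted p = 2.1e-04 with the preset and 0.47 with an estimated correlation). Relative to wild-type sham their mean was 0.00, 0.11 and 1.32 on the sham arrays and 1.35, 1.11 and 1.09 on the CLP arrays, so array 3 of sham lay at the level of CLP. Ciliated cell markers had 6 of 13 down with a median of -0.71 (8 adjusted over the list alone; adjusted p = 0.0013 with the preset and 0.47 with an estimated correlation), led by Tekt4 (-1.52) and Ccdc39 (-1.53). Cardiac muscle markers had 10 of 12 down with a median of -0.99 (11 adjusted over the list alone; adjusted p = 2.1e-04 with the preset and 0.47 with an estimated correlation), led by cardiac actin, Actc1 (-1.11). Smooth muscle markers had 7 of 10 with -0.54 (9 adjusted over the list alone; adjusted p = 0.0074 with the preset and 0.31 with an estimated correlation). Of the tachykinin system 4 of 7 measured genes fell: Calcrl, the receptor subunit for calcitonin gene-related peptide (-1.25 ± 0.23), its ligand Calcb (-1.11 ± 0.25) and the peptidases Ace (-0.60 ± 0.14) and Dpp4 (-0.40 ± 0.12), with no list call (adjusted p = 0.17). Dpp4 was called in 8 of 12 runs with 1 array left out, with an adjusted p up to 0.10 without array 1 of knockout-labelled sham. The interferon gamma list was called (adjusted p = 0.040 with the preset and 0.68 with an estimated correlation) but not without array 3 of knockout-labelled sham (adjusted p = 0.53), and immediate early genes were not called without that array either (adjusted p = 0.24). With only the 2 groups in the model 2669 probe sets were called, so the total of 7172 is not set against the wild-type count.

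Whether the response differed between genotypes was tested by the interaction, the knockout-labelled response minus the wild-type response. Neutrophil-attracting chemokines were not called as different. The lists of acute phase, granulocyte precursor and matrix genes were called as responding more in knockout-labelled mice with the preset correlation, but not with an estimated one (adjusted p = 0.24, 0.12 and 0.44). The interaction was called for 995 probe sets, 416 above 0 and 579 below, of which 224 and 347 were at least 2-fold. With arrays centred on their medians the balance turned to 651 above and 399 below, so the excess below 0 is relative to the deposited scaling. Of these, 968 were also called in the knockout-labelled response, 22 in the wild-type response and 11 in both. Cxcl2 had an interaction of -0.19 ± 0.65 (adjusted p = 0.89), Cxcl3 0.48 ± 0.49 (0.60), Il1b -0.23 ± 0.50 (0.82) and Trem1 -0.10 ± 0.37 (0.90), none of them called. The largest was in Orm1 (1451054_at), whose signal was 26.5 ± 13.4 (SD) and 1013 ± 768 in knockout-labelled sham and CLP against 18.96 ± 1.53 and 21.7 ± 4.86 in the wild type (4.65 ± 0.77 SE, adjusted p = 0.012). Saa3 had an interaction of 3.41 ± 0.61 (adjusted p = 0.016, and 0.056 without array 2 of wild-type CLP), with a wild-type response of 1.94 ± 0.43 (adjusted p = 0.058), and Camp one of 3.398 ± 0.52 (adjusted p = 0.010), with 2.14 ± 0.37 in the wild type. In wild-type sham Camp read 205 to 366 and Ngp 448 to 740. In knockout-labelled sham they read 38.7 to 134 and 261 to 405, so a lower sham level forms part of their interactions. The scavenger receptor Msr1 (3.58 ± 0.48, adjusted p = 0.0062), the venular chemokine-binding receptor Ackr1 (3.37 ± 0.53, 0.011), Timp1 (2.67 ± 0.27, 0.0017) and Ngp (2.48 ± 0.27, 0.0021) were called in all 12 runs with 1 array left out, as were Orm1, Camp, Hspa1b, Gli2 and Cass4. Il6 (3.99 ± 0.93, adjusted p = 0.035) was called in 3 of those runs, Il1rn (3.32) in 3, the aggrecanase Adamts4 (3.52) in 2 and Selp, the platelet and endothelial selectin (2.78), in 2. Without array 2 of wild-type CLP the adjusted p was 0.10 for Il6, 0.078 for Il1rn, 0.11 for Adamts4 and 0.12 for Selp. Below 0 were Hspa1b (-4.08 ± 0.70, adjusted p = 0.014), Gli2 (-2.63 ± 0.42, 0.011, or -1.34 with the larger pseudocount) and the neutrophil granule protease Mmp9 (-0.91 ± 0.18, 0.023). In the wild type Hspa1b stood at 401 ± 189.8 after sham and 561 ± 108 after CLP. Mmp9 rose in the wild type by 1.65 and in knockout-labelled mice by 0.74. Its interaction was called in 5 of the 12 runs, with an adjusted p of 0.077 without array 2 of wild-type CLP.

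**Figure D3:**
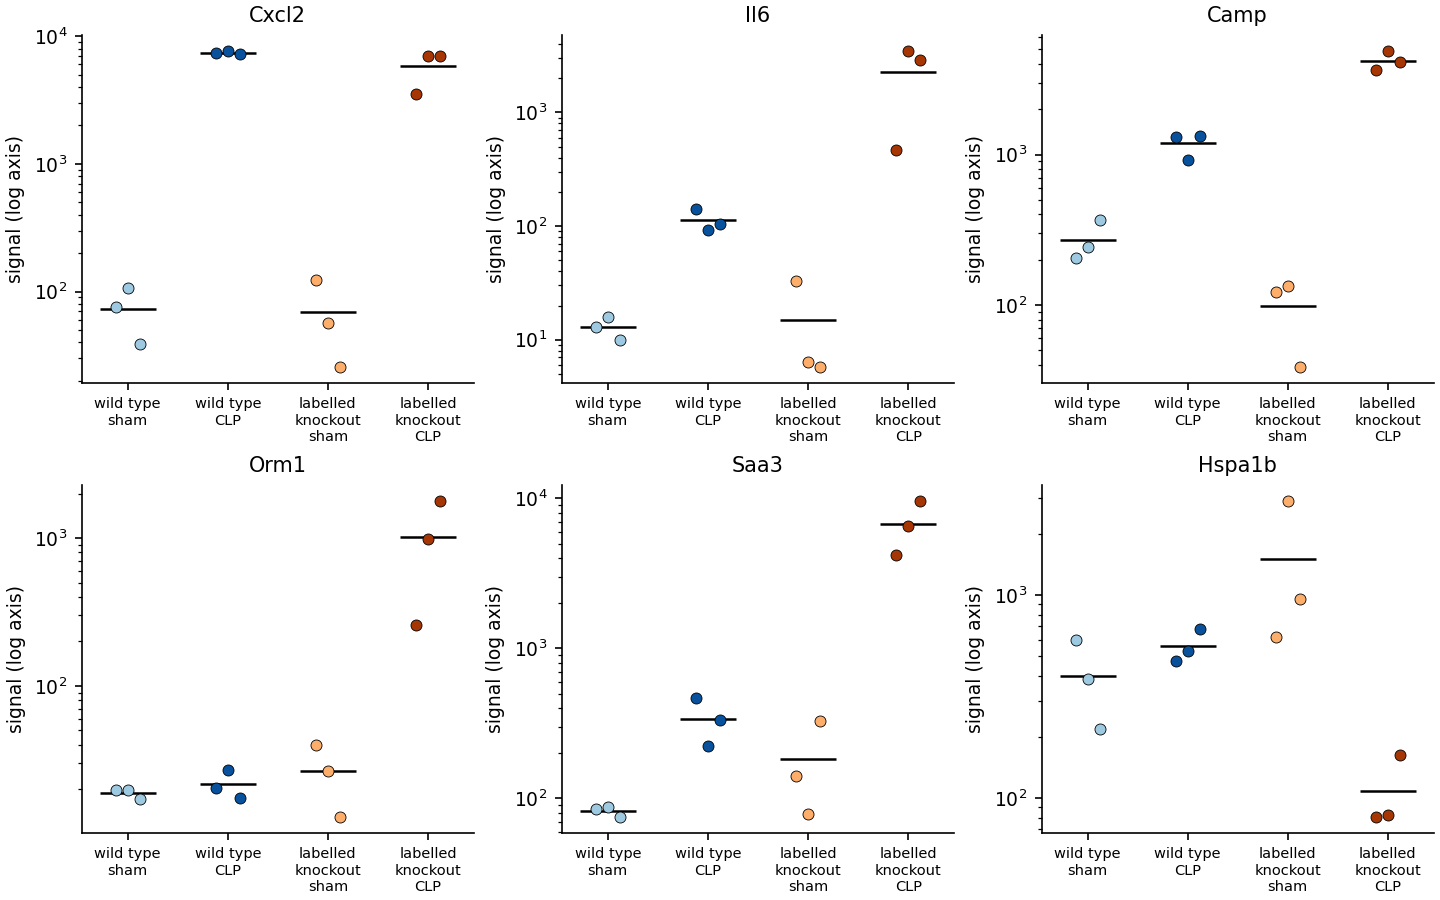
Signal (log axis) of Cxcl2, Il6, Camp, Orm1, Saa3 and Hspa1b on each of the 12 arrays, by group; points are arrays and lines are group means. Cxcl2 rises in both genotypes, while Orm1 and Saa3 reach their highest signals on the knockout-labelled CLP arrays.

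Of 43 lists, 15 had an interaction above 0 and 3 below 0 with the preset, none with an estimated correlation. Acute phase proteins had 9 of 16 called (12 adjusted over the list alone) with a median interaction of 1.77 (adjusted p = 4.0e-09 with the preset and 0.24 with an estimated correlation). Granulocyte precursor markers had 3 of 5 (4 adjusted over the list alone) with 2.03 (adjusted p = 2.1e-05 with the preset and 0.12 with an estimated correlation). Relative to wild-type sham their mean was -0.53 in knockout-labelled sham, 2.74 in knockout-labelled CLP and 1.27 in wild-type CLP. A lower sham level thus forms part of that interaction. Mature neutrophil markers were not called (median -0.10, adjusted p = 0.78), nor were neutrophil-attracting chemokines (0.29, 0.36). CC chemokines had a median of 1.10 with 1 member called, Ccl17 (2.88 ± 0.36; adjusted p = 1.8e-04 with the preset and 0.44 with an estimated correlation). Of 16 matrix genes only Timp1 and Adamts4 were called above 0 and Mmp9 below (6 and 1 adjusted over the list alone; adjusted p = 0.0036 with the preset and 0.44 with an estimated correlation). In the antioxidant list the mitochondrial dismutase Sod2 (1.73 ± 0.29), the cystine transporter Slc7a11 (2.19) and Hmox1 (1.80) were above 0 and catalase, Cat (-0.71), below (adjusted p = 0.0033 with the preset and 0.24 with an estimated correlation). Without array 2 of wild-type CLP the adjusted p was 0.054 for Sod2, 0.099 for Slc7a11, 0.11 for Hmox1 and 0.070 for Cat. Alveolar macrophage markers (0.72; adjusted p = 1.8e-04 with the preset and 0.54 with an estimated correlation) and cell cycle genes (0.51; adjusted p = 0.0013 with the preset and 0.54 with an estimated correlation) were called as lists with no member called. Cardiac (-0.93; adjusted p = 3.3e-04 with the preset and 0.54 with an estimated correlation), smooth muscle (-0.59; adjusted p = 0.0076 with the preset and 0.48 with an estimated correlation) and ciliated markers (-0.53; adjusted p = 0.0027 with the preset and 0.57 with an estimated correlation) were below 0. Relative to wild-type sham the means of these lists went from 1.31 to 0.36, 0.21 to -0.33 and 0.53 to -0.26 in knockout-labelled mice, and to -0.09, 0.03 and -0.07 in wild-type CLP. With the preset, the cardiac and ciliated lists were called higher in knockout-labelled sham than in wild-type sham, and the smooth muscle list was not. On array 3 of knockout-labelled sham the smooth muscle mean was 0.006 and the ciliated mean 0.02. The remaining called lists were proinflammatory cytokines (0.62), feedback regulators (0.50), leukocyte adhesion (0.41), type I interferon (0.68), pattern recognition (0.33), hypoxia (0.34), glucocorticoid-responsive (0.26) and coagulation genes (0.12), with estimated-correlation adjusted p from 0.24 to 0.57. The last 3 were not called with quantile normalisation (adjusted p = 0.055, 0.089 and 0.090) and were called in 10, 8 and 11 of 12 runs with 1 array left out (adjusted p up to 0.083, 0.13 and 0.057). The glucocorticoid-responsive mean, relative to wild-type sham, was 0.34 in wild-type CLP, -0.50 in knockout-labelled sham and 0.20 in knockout-labelled CLP. Its level in knockout-labelled CLP was thus not above wild-type CLP, and its interaction reflects the lower sham level. Proinflammatory cytokines were not called with the stricter filter (adjusted p = 0.21). The type I interferon list rests on few arrays: relative to wild-type sham its mean was 0.54, 1.32 and 2.25 on the knockout-labelled CLP arrays and 0.58, 0.21 and 0.71 on the sham arrays. Without array 3 of knockout-labelled CLP the median interaction fell to 0.26 for that list and to 0.16 for pattern recognition. The median of feedback regulators was 0.24 without array 2 and 1.04 without array 1 of that group. In the tachykinin system no interaction was called (Ace -0.77 ± 0.20, adjusted p = 0.052, Calcrl -1.15 ± 0.33, adjusted p = 0.069), but without array 1 of knockout-labelled CLP both were (adjusted p = 0.025 for Ace and 0.0077 for Calcrl).

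**Figure D4:**
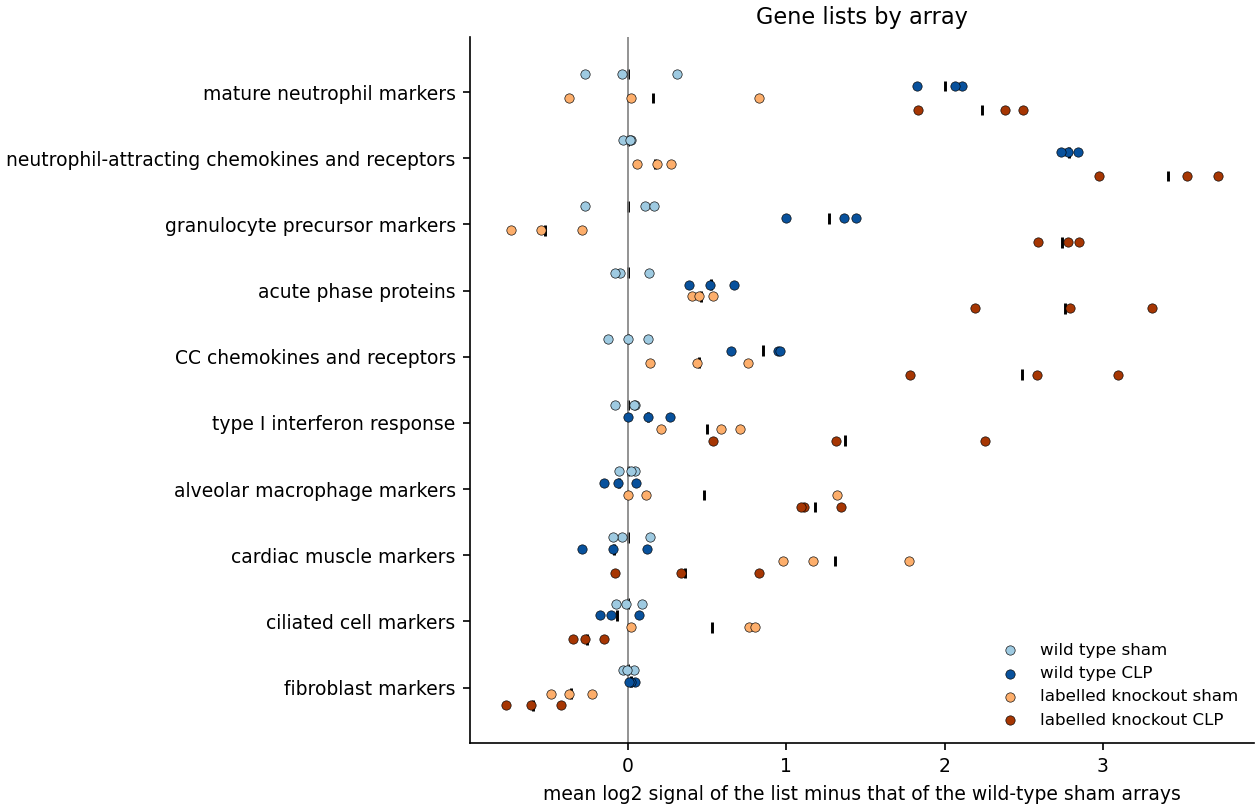
Mean log2 signal of the members of 10 gene lists on each array, minus the mean of the wild-type sham arrays (log2 units); points are arrays and ticks are group means. Mature neutrophil markers rise in both genotypes, and acute phase proteins rise to 2.19 to 3.31 in knockout-labelled CLP against 0.39 to 0.67 in wild-type CLP.

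The size of the response was compared over 4927 probe sets called for CLP on average, 1808 risen and 3119 fallen. Their mean change was 0.99 in knockout-labelled mice and 0.37 in the wild type on the log2 scale, a ratio of 2.67 (two-sided exact permutation p = 0.010 over 400 assignments). Genotypes also differed after sham, so this p does not test equal responses alone. The ratio was 2.17 for those that rose (permutation p = 0.050) and 3.22 for those that fell (permutation p = 0.005, the smallest possible). Over the 725 changed at least 2-fold it was 1.94 (permutation p = 0.055). Across probe sets the responses correlated with r = 0.48 and rho = 0.30, where probe sets are not independent replicates, and r was 0.27 with no filter. Of the 200 that rose in the wild type 164 also rose in knockout-labelled mice, against 20.8 for independent calls, and of the 33 that fell 28 also fell, against 6.20. Both responses were called with the same estimate of spread per probe set, which can by itself raise these overlaps. Of the 233 probe sets called in the wild type only 121 had a larger change in knockout-labelled mice, although choosing them by their wild-type change favours the wild type. The 4927 were chosen by the average change, which is independent of the difference only where both genotypes spread alike. Knockout-labelled arrays spread more, so that choice may favour the knockout-labelled response.

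The interaction count moved with most arrays. Without array 1, 2 or 3 it was 205, 181 or 174 for wild-type sham, 237, 107 or 257 for wild-type CLP and 448, 306 or 3284 for knockout-labelled sham, and it was 2613 or 246 without array 1 or 2 of knockout-labelled CLP. The count for CLP on average was 3232 without array 1 of wild-type sham and 3192 or 3261 without array 1 or 3 of wild-type CLP.

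Knockout-labelled and wild-type mice were compared after sham surgery to see how the lungs differed without sepsis. The largest differences were in single genes, and no gene list was called with an estimated correlation. The labels give a strain for the wild type only, so these differences belong to genotype and strain together. Of the probe sets tested 1101 were higher and 949 lower in knockout-labelled sham, 529 and 332 of them at least 2-fold. The balance depends on the scaling: 944 were higher and 1230 lower with arrays centred on their medians, and 1069 and 1097 with quantile normalisation. Beside Tac1, one of the largest rises was in Pam (1418908_at), the enzyme that amidates peptide hormones, at 51.04 ± 5.11 (SD) in the wild type and 1262 ± 116 in knockout-labelled sham (4.54 ± 0.14 SE, adjusted p = 9.5e-10). Genes of the antiviral Trim family lay on both sides, with Trim30d at 4.52 ± 0.42, Trim5 at 4.45 ± 0.27 and Trim12c at -5.55 ± 0.28. The lower group of each reads near the pseudocount, and with a pseudocount of 50% of the median the differences were 2.85, 3.12 and -3.96, and 2.52 for Clca1 below. The class II chains H2-Eb1 (-3.54 ± 0.19, adjusted p = 2.4e-07) and H2-Ea (-3.17 ± 0.26, adjusted p = 1.1e-05, read by its other probe set) were lower, while H2-Aa (0.79 ± 0.10) was higher, and the class II list was not called (adjusted p = 0.15). Clca1, a product of mucous cells (4.27 ± 0.53), and Reg3g, an antibacterial lectin (2.61 ± 0.33), were higher. Of 43 lists 8 lay higher and 5 lower with the preset. Cardiac muscle markers had 11 of 12 higher, both overall and adjusted over the list alone, with a median of 1.37 (adjusted p = 7.4e-11 with the preset and 0.48 with an estimated correlation). Actc1 went from 482 ± 35.8 to 2943 ± 676 (2.58 ± 0.17). Ciliated (3 of 13; adjusted p = 0.0035 with the preset and 0.88 with an estimated correlation), club cell (4 of 12; adjusted p = 0.030 with the preset and 0.88 with an estimated correlation) and interferon gamma genes (3 of 16, 9 adjusted over the list alone; adjusted p = 2.1e-04 with the preset and 0.88 with an estimated correlation) were higher. These rest on few arrays: relative to wild-type sham the mean on knockout-labelled sham arrays 1, 2 and 3 was 0.76, 0.80 and 0.02 for ciliated and 2.10, 0.89 and 0.31 for interferon gamma genes. Fibroblast markers (4 of 15 down; adjusted p = 2.6e-04 with the preset and 0.51 with an estimated correlation), endothelial markers (3 of 20; adjusted p = 5.3e-04 with the preset and 0.36 with an estimated correlation) and glucocorticoid-responsive genes (4 of 16; adjusted p = 0.0018 with the preset and 0.36 with an estimated correlation) were lower. The other 6 called lists (acute phase, type I interferon, pattern recognition and monocyte genes higher, circadian clock and nerve and glia genes lower) had estimated-correlation adjusted p from 0.48 to 0.90. Pattern recognition and monocyte markers were not called without array 3 of knockout-labelled sham (adjusted p = 0.31 and 0.22), and club cell markers not without array 2 of that group (adjusted p = 0.16). Acute phase and type I interferon genes were not called without array 1 of that group (adjusted p = 0.056 for both) or with suffix probe sets left out (0.087 for both). Circadian clock genes were called in 4 of 12 runs with 1 array left out (adjusted p up to 0.29) and in 4 of 11 other alternatives (up to 0.13). Nerve and glia markers were called in 9 of 12 runs (up to 0.091) and in 6 of 10 other alternatives (adjusted p = 0.50 with no filter). The count of 2050 was 1149, 1141 or 1130 without array 1, 2 or 3 of wild-type sham.

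After CLP the comparison asked how septic lungs differed between genotypes, which adds the baseline difference to the difference in response. With the preset correlation, lists of acute phase, interferon and macrophage genes lay higher and lists of fibroblast and endothelial markers lower, but none was called with an estimated correlation. Here 3102 probe sets were higher and 4144 lower in knockout-labelled CLP, 1024 and 1216 at least 2-fold, and without array 2 of wild-type CLP the total fell from 7246 to 4553. Both genotype comparisons shared 595 of the higher probe sets, against 139 for independent calls, and 646 of the lower, against 160.0. The comparisons use the same estimate of spread per probe set, which can by itself raise such an overlap. Tac1 (4.97 ± 0.33 SE), Pam (4.60 ± 0.14), Trim30d (4.95 ± 0.42) and Trim12c (-5.91 ± 0.28) were again among the largest. Beside them stood Fgg, which encodes the fibrinogen gamma chain (5.00 ± 0.44, adjusted p = 1.3e-05), Orm1 (4.96 ± 0.54, adjusted p = 6.5e-05) and Saa3 (4.28 ± 0.43, adjusted p = 3.2e-05). With the larger pseudocount the differences were 3.51 for Fgg, 3.39 for Trim30d and -4.10 for Trim12c, whose lower groups read near the floor, against 4.35 for Orm1 and 4.26 for Pam. Lower were the matrix protein gene Tnn (-3.77 ± 0.47), Gli2 (-3.34 ± 0.29, or -1.91 with the larger pseudocount) and Lrat (-3.27 ± 0.71). Of 43 lists 15 lay higher and 2 lower with the preset. Acute phase proteins had 13 of 16 higher with a median of 1.98 (adjusted p = 7.7e-11 with the preset and 0.28 with an estimated correlation). Type I interferon genes had 14 of 21 higher with 1.11, or 0.70 without array 3 of knockout-labelled CLP (17 adjusted over the list alone; adjusted p = 4.0e-07 with the preset and 0.44 with an estimated correlation). Alveolar macrophage markers had 11 of 13 higher with 0.95, led by the scavenger receptor Marco (4.04 ± 0.60, or 2.73 with the larger pseudocount; adjusted p = 3.0e-05 with the preset and 0.44 with an estimated correlation). The other 12 higher lists had medians from 0.36 to 1.92 and estimated-correlation adjusted p from 0.28 to 0.57. Among these, cardiac muscle markers and proinflammatory cytokines were not called without array 3 of knockout-labelled CLP (adjusted p = 0.057 and 0.059), proinflammatory cytokines not with the stricter filter (0.15) and coagulation genes not with quantile normalisation (0.057). Fibroblast markers had 10 of 15 lower with a median of -0.74 (11 adjusted over the list alone; adjusted p = 1.5e-04 with the preset and 0.33 with an estimated correlation), among them the collagen Col1a1 (-1.37 ± 0.19). Endothelial markers had 12 of 20 lower with -0.46 (13 adjusted over the list alone; adjusted p = 0.0059 with the preset and 0.28 with an estimated correlation), led by the angiopoietin receptor Tek (-1.33 ± 0.17), with Sox18 (1.68, adjusted p = 0.018, and 0.077 without array 1 of wild-type CLP) and Esam (0.26) against them. The endothelial list was not called with suffix probe sets left out (adjusted p = 0.10). In the tachykinin system Ace (-1.29 ± 0.14, adjusted p = 6.6e-05), which degrades substance P, was lower after CLP and also after sham (-0.52 ± 0.14, adjusted p = 0.039), where it was called in 3 of 12 runs with 1 array left out (adjusted p = 0.15 without array 2 of wild-type sham). Mme and Ramp1 were not called in the 5 comparisons with all arrays at equal weight. Without array 3 of knockout-labelled CLP the rise of Ramp1 after CLP was called (0.51, adjusted p = 0.0065), and without array 1 of that group Mme was called lower after CLP (-0.53, adjusted p = 0.014).

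On average over surgery 3252 probe sets were higher and 3765 lower in knockout-labelled mice, and on average over genotype 1808 rose and 3119 fell after CLP. With arrays centred on their medians the share of rises among the latter went from 36.7% to 59.7%.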

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

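Of the tests below, those on the liver transcripts, on H2-Ea, on the other Tac1 probe set and on splits after removal of the average genotype difference were chosen only after the result was seen, and that on the number of chromosomes after the counts of calls but before its own value.

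The results in this paragraph were singled out because a test of the difference in response between genotypes called them. The ratios of 2.17 and 1.94 did not pass and are given beside the others. The interaction was called for 995 probe sets, and the ratio of the knockout-labelled to the wild-type response was 2.67 over all probe sets called for CLP on average, 3.22 over those that fell, 2.17 over those that rose (permutation p = 0.050) and 1.94 over those changed at least 2-fold (permutation p = 0.055). Which probe sets count as fallen depends on the scaling, with 3119 as deposited and 1824 with arrays centred on their medians. Lists with a positive median interaction (log2) were acute phase proteins (1.77), granulocyte precursor markers (2.03), CC chemokines (1.10), alveolar macrophage markers (0.72), matrix proteases and inhibitors (0.70), oxidant and antioxidant enzymes (0.68), type I interferon genes (0.68, and 0.26 without array 3 of knockout-labelled CLP), proinflammatory cytokines (0.62), cell cycle genes (0.51), feedback regulators (0.50), leukocyte adhesion (0.41), hypoxia (0.34), pattern recognition (0.33), glucocorticoid-responsive (0.26) and coagulation genes (0.12). Ciliated (-0.53), smooth muscle (-0.59) and cardiac muscle markers (-0.93) had a negative median. None of these lists was called with an estimated correlation. The largest interactions above 0 were in Orm1 (4.65), Tmem45a2 (4.004), Il6 (3.99), Msr1 (3.58), Adamts4 (3.52), Saa1 (3.50), Saa3 (3.41), Camp (3.398), Ackr1 (3.37) and Il1rn (3.32). The largest below 0 were in Hspa1b (-4.08), Wnt3a (-3.62), Hspa1a (-2.66), Gli2 (-2.63), Cass4 (-2.61), Lbh (-2.58), Klra17 (-2.36), Sstr4 (-2.19), Ccn5 (-2.18) and Vgll3 (-2.12). Tmem45a2 and Gli2 were at 2.66 and -1.34 with a pseudocount of 50% of the median, since some groups read near the floor. Without array 2 of wild-type CLP the calls of Tmem45a2, Il6, Adamts4, Saa1, Saa3, Il1rn, Wnt3a, Hspa1a, Lbh, Klra17, Sstr4, Ccn5 and Vgll3 ended, with adjusted p from 0.056 to 0.11.

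Other splits of the arrays bear on whether chance can be excluded. For the 995 interaction calls it could not be: 6 of 100 splits gave as many, with 2879 in the highest other split. In the other splits with that many calls the CLP arrays stayed whole by genotype, kept or fully exchanged, and 1 sham array of each genotype changed sides. Splits that mixed the genotypes among the CLP arrays gave at most 1 call. Those with many calls carry the genotype difference, so they point to a structure of the samples. The average genotype difference of each probe set was then subtracted. After that 1 of 100 splits, the real one, gave as many as its 990, and the highest other gave 1. The difference subtracted was estimated from the real groups, which can favour the real split. This test was also chosen after the planned one, so chance is not excluded by it. For the 18 lists with an interaction 27 of 100 splits gave as many and the highest other gave 27 lists, so chance is not excluded for that count.

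The larger response in knockout-labelled mice was weighed against technical sources. Dependence on a single array is argued against by the ratio with each array left out, whose lowest value was 2.25, and dependence on scaling by a ratio of 2.58 with quantile normalisation, the lower of the quantile and median-centred values. Liver RNA in the knockout-labelled CLP samples is argued against as the source of the larger response: abundant liver transcripts (Alb, Apoa1, Apoa2, Ttr and Ahsg, 11 probe sets) read at most 1.16 times the median of the array in that group. The 13 of 16 hepatocyte markers on the array had a median interaction of 0.14 with none called. Only 2 of these 13 passed the filter, so these values rest mostly on weak signals. Fabp1, also in the alveolar macrophage list, read 475 in knockout-labelled CLP and 383 in knockout-labelled sham, against 143 and 124 in the wild type. Ambp alone was called up by CLP in knockout-labelled mice (3.23, adjusted p = 0.0083), so a trace of liver RNA behind single genes is not excluded. Genotype, strain, the severity of the surgery in each animal and the lower 3-prime to 5-prime actin ratio of these arrays stay open too; the Gapdh ratio was 0.756 on them and 0.764 in knockout-labelled sham.

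The Tac1 signal was higher on the arrays labelled knockout. An exchange of the genotype labels is argued against by H2-Ea, which mice of the Balb/c haplotype express: its lowest signal on the wild-type arrays was 28.2 times its highest on the knockout-labelled arrays by the more strongly expressed probe set and 4.68 times by the other. This rests on the strain label of the wild type. Whether a transcript of the altered locus keeps the part that the raised Tac1 probe set reads was not decided: the other Tac1 probe set was at most 0.435 of the array median on all 12 arrays. No position of the probe sets or of the disruption was available, and a strain difference in Tac1 expression stays open too.

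Many probe sets differed between genotypes after both surgeries. If donor-strain alleles next to Tac1 were the main source, the chromosome of Tac1 (6) would hold most of the strong calls, but it held 12.1% of those at least 4-fold (11 of 91), where it holds 5.34% of the genes tested. Among the 50 genes nearest to Tac1, 42% were called against 30.2% of the others (Fisher exact p = 0.088, two-sided), so a part near the locus is not excluded. Chromosome 6 had the highest share of its tested genes among these calls (1.74%), followed by chromosome 1 (1.48%). Calls of at least 4-fold lay on 19 chromosomes. A set of 91 genes could spread so widely under other causes too, so this number does not single out a strain difference. Strain and genotype are confounded by the design, and a biological effect of the genotype stays open as untested.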

How the results depend on the processing

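All alternatives in this part were planned, and no tests in it were chosen only after the result was seen. The limits were a factor of 1.5 for a count and the same side of a permutation p of 0.05 for the ratio. For the correlation the limit was a standard error of 0.065, from the runs with an array left out. Of 339 alternative values of the counts, ratio and correlation 292 stayed within their limits, 37 were weaker, 9 stronger and 1 moved, and none reversed. For the interaction count 9 of 24 stayed, 12 were weaker and 3 stronger. For CLP in the wild type 15 of 25 counts stayed, 6 were weaker and 4 stronger.

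The cause was not tested for any shift below except where the alternative tests fewer or more probe sets (no filter 45037, suffix left out 17910) or asks for more. With at least a 2-fold change the counts were 2159 (CLP in the knockout-labelled), 571 (interaction), 861 (genotype after sham), 2240 (genotype after CLP), 1233 (genotype on average) and 725 (CLP on average), and the ratio was 1.94. With array weights they were 1308 (CLP in the wild type), 5834 (interaction), 4071 (sham) and 9481 (CLP on average). With only the 2 groups compared, CLP gave 1281 in the wild type and 2669 in the knockout-labelled. The interaction count was 557 with no filter and 580 with suffix probe sets left out, and the correlation of responses was 0.27 with no filter. With an estimated correlation the lists called were 4 for CLP in the wild type and 0 in each of the other 4 comparisons.

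With each array left out, which leaves 2 in its group and pools the spread over all groups, the counts ran from 51 to 432 (CLP in the wild type), 4977 to 8767 (CLP in the knockout-labelled), 107 to 3284 (interaction), 1130 to 2599 (sham), 4553 to 9004 (genotype after CLP), 5418 to 7748 (genotype on average) and 3192 to 6928 (CLP on average). The ratio ran from 2.25 to 3.29 and the correlation from 0.43 to 0.51. Lists called ran from 16 to 21, 24 to 26, 16 to 24, 11 to 13 and 15 to 21 in the order of the first 5 comparisons.

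With the replicate number as a block the counts were 216, 7053, 886, 1928, 7098, 6911 and 4757 and the ratio 2.67 (permutation p = 0.015). Same-numbered arrays of different groups correlated at r from -0.10 to 0.12 after group means were removed, with 2 of 18 pairs above 0.1. In 7 of the 18 the own number was the best match. No clear pairing by number was seen, which does not exclude one. Of 2159 alternative values of called lists 1993 kept the call and 166 did not, 86 of them with an estimated correlation. Of 19360 values of named genes 17952 stayed on their side of the threshold, 1204 lost a call, 959 of these with an array left out, and 204 gained one, with no reversal. Camera takes no robust setting, so robust estimation has no list values. Without detection calls, signal over background could not be read, which limits what can be said of weakly expressed genes.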

Other observations

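No tests in this part were chosen only after the result was seen.

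For comparisons of 3 arrays with 3 only 10 splits exist, too few for a share under 0.05. The real split gave 233 probe sets for CLP in the wild type and the highest other 0, with 1 split as large. The values were 7172 and 4 (1 split) for CLP in the knockout-labelled, 2050 and 0 (1 split) for genotype after sham, and 7246 and 0 (1 split) for genotype after CLP. For lists called they were 18 and 19 (2 splits), 24 and 26 (2 splits), 13 and 14 (4 splits) and 17 and 28 (4 splits) in the same order. In each of these comparisons another split called more lists than the real one, so the counts of lists do not set the real groups apart. For genotype on average 1 of 100 splits, the real one, gave 7017 or more, with 2879 in the highest other, and for CLP on average 1 of 100 gave 4927 or more, with 2887. That share is under 0.05, so a random grouping of these arrays is argued against for these last comparisons. The splits regroup arrays that may not come from separate animals, so chance differences between animals are not excluded.

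Eif2s3y, a gene of the Y chromosome, read 288 to 394 on all 12 arrays. The higher of the Xist probe sets read 35.5 to 59.0. The 3-prime to 5-prime ratio of Gapdh was 0.678 to 0.913. The mean of the cardiac muscle markers relative to wild-type sham was 0.98, 1.78 and 1.17 on the knockout-labelled sham arrays and -0.08, 0.33 and 0.83 on the knockout-labelled CLP arrays. BC018473 read 7.63, 88.5 and 479 on the knockout-labelled sham arrays.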
